A study of Mus musculus with 16 samples.

How the data were processed

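RNA from liver and quadriceps of wild-type and Klf15-null female mice, 4 to 5 months old and fasted for 18 h, was measured on 16 Affymetrix Mouse430A_2 arrays, 1 array per sample. Klf15 is a zinc finger transcription factor of the Kruppel-like family. Each of the 4 groups held 4 arrays, and the group and replicate number of each array were taken from its sample title. Wild-type samples carried the numbers 1 to 4 and knockout samples the numbers 5 to 8 in both tissues.

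The deposited values were linear signal intensity, 1 per probe set, made by the authors with GCOS, the Affymetrix array software, per the submitters' processing notes. The version of that software, its summary method and its scaling settings are not given in the sources used here. Fluidics station, fluidics module and scan day were read from the deposited experiment record of each array and used only as batch labels. The table held 22690 probe sets, of which 64 were controls. Of the 22626 others, 20380 were paired with 1 gene symbol, 691 with several and 1555 were unnamed in the platform annotation used here. Symbols were set against the RefSeq gene table of assembly GRCm38.p6 through the Entrez identifier, which held 12369 of the 12393 named genes. That table was used for names and for which genes neighbour each other.

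The median signal lay between 41.6 and 48.9 on the liver arrays, a ratio of 1.18, and between 15.6 and 59.2 on the quadriceps arrays, a ratio of 3.79. By a rule set beforehand, arrays were scaled to their median only where medians within a tissue differed by more than 1.5 times, so liver signals were used as deposited and quadriceps arrays were multiplied by factors from 0.678 to 2.57. Signals were then transformed as log2(signal + 16), which understates the change of dim genes. No detection calls were used, and the number of arrays limits the precision. Each gene was represented by the probe set with the highest mean over the 16 arrays, and genes entered a test when their mean was at or above the 40th percentile of the measured probe sets, a signal of 24.0 in liver and 22.6 in quadriceps. Probe sets with several symbols or none stayed out of the gene tests.

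Knockout minus wild type was fitted in each tissue alone with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). The difference between the tissues was fitted over 16 arrays as the knockout effect in liver minus that in quadriceps. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The lists of genes (22 lists holding 538 distinct members, 482 of them on named probe sets) and 13 lists of cell type markers were tested with limma's camera at a preset correlation of 0.01 where at least 4 members were tested, adjusted over the lists of a family. Camera with an estimated correlation and fry were run beside it. Overlap between tissues was set against the number expected for independent lists and tested with Fisher's exact test, one-sided. Figures were drawn with matplotlib 3.10.9.

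Before the values were seen, a rule fixed the genes to be named. It took Klf15, the 10 largest rises and the 10 largest falls past the threshold in each tissue among genes whose groups did not overlap, up to 4 members of each list with the smallest p plus members past the threshold where a list is described, the 5 largest positive and 5 largest negative interaction terms, and up to 10 genes past the threshold in both tissues. Genes named outside it are said to be so.

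The fits were tested on simulated data with the observed means and spreads and 200 genes changed by known factors. Values were drawn independently, with the same spread for a gene in all groups of a fit. The simulations hold no array that stands apart, so their false calls do not describe data with such an array. In the liver simulation over 7989 genes, 38 of 73 genes changed 1.5-fold, 58 of 67 changed 2-fold and 60 of 60 changed 4-fold were recovered, with 17 false calls among 173, a larger share than the threshold of 0.05 states. In the quadriceps simulation over 7991 genes, 4 of 69, 41 of 64 and 66 of 67 were recovered, with 8 false calls among 119. In the interaction simulation over 8966 genes, 6 of 70, 23 of 69 and 56 of 61 were recovered, with 3 false calls among 88.

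The alternatives were other pseudocounts (1 and 64), no filter and a filter at the 60th percentile, quantile normalization, median centring of log2 values, no variance trend, the mean of all probe sets of a gene, every probe set as its own feature, all 16 arrays in 1 fit with and without the replicate number as a block, the scan day as a block, the other list tests and leaving out each array in turn. Trimmed-mean scaling (2% from each end), no scaling, quantile normalization or trimmed-mean scaling without knockout quadriceps 8, the fluidics module as a block and the list test of the interaction, over all its genes and over those tested in both tissues, and the test of the Kruppel-like factor list without Klf15 were chosen after seeing the data.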

Results

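Gene expression was measured in liver and quadriceps muscle of fasted wild-type and Klf15-null female mice, to ask which transcripts differ without Klf15 in each tissue and whether the tissues differ in this. Each group held 4 arrays. Spearman correlations between arrays lay between 0.946 and 0.960 in liver and between 0.882 and 0.956 in quadriceps. Knockout quadriceps 8 stood apart: its median signal was 15.6, against 32.5 to 59.2 on the other quadriceps arrays, its 100 brightest probe sets held 21.3% of the signal, against at most 16% on the others, and it was scanned 3 days after the others. Its Gapdh 3'/5' ratio, a sign of RNA quality, was 1.09, against 0.785 to 0.790 on the other knockout and 0.855 to 0.937 on the wild-type quadriceps arrays, so without knockout 8 this ratio separates the genotypes. Within each tissue, all wild-type arrays were washed on fluidics station 2 and all knockout arrays on station 1, so station and genotype cannot be told apart. The labels number the samples without saying that each is a separate animal, so p-values measure the spread between these samples. Signals are given as mean ± SD over n = 4 arrays, and fold changes are knockout minus wild type on the log2(signal + 16) scale with the standard error (SE).

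Klf15 itself was examined first. In liver its signal was 1093 ± 195 in wild type and 165 ± 23.6 in knockout, a log2 fold change of -2.60 (SE 0.14, adjusted p = 9.87e-08, limma). In quadriceps the scaled signal was 656 ± 95.0 and 57.3 ± 33.5, a log2 fold change of -3.33 (SE 0.29, adjusted p = 3e-06, limma). All knockout arrays lay below all wild-type arrays in both tissues. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal was not interpreted.

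**Figure D1:**
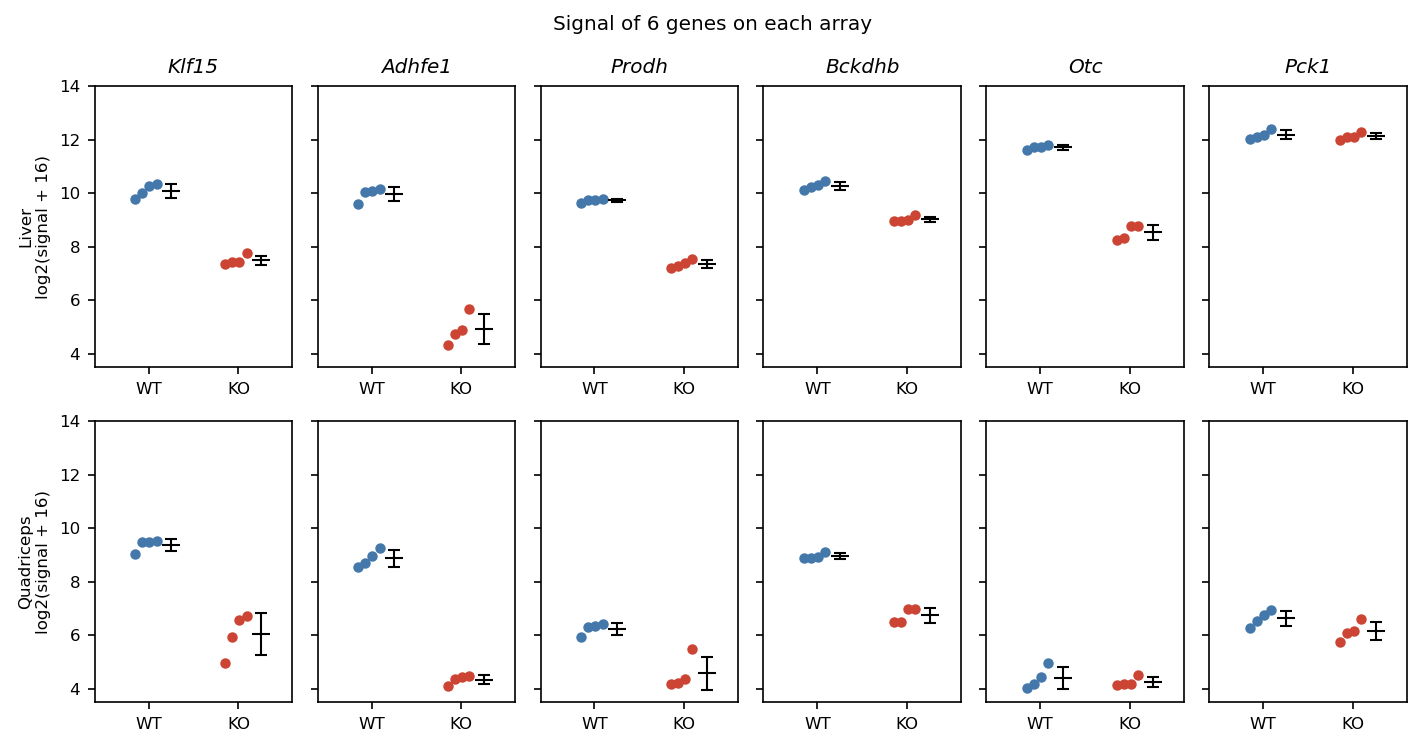
Signal of 6 genes as log2(signal + 16) on each liver array (top) and quadriceps array (bottom), with wild-type arrays in blue, knockout arrays in red, points of a group ordered by value, and black marks for the mean ± SD of 4 arrays. Klf15, Adhfe1, Prodh and Bckdhb were lower in knockout in both tissues and Otc in liver, Pck1 passed the test in neither tissue, and Otc in quadriceps was below the filter and not tested.

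In knockout liver, the largest falls were in Adhfe1, an alcohol dehydrogenase that oxidises 4-hydroxybutyrate, Serpinb1a, an inhibitor of neutrophil proteases, Serpina6, which encodes corticosteroid-binding globulin, Sucnr1, the succinate receptor, and Otc, the urea cycle enzyme that makes citrulline. Adhfe1 went from 997 ± 158 to 16.1 ± 13.5 (log2 fold change -5.05, SE 0.23, adjusted p = 4.43e-08, limma) and Serpinb1a from 702 ± 302 to 5.97 ± 5.64 (-4.97, SE 0.26). Both knockout means lay below the signal of 24.0 at which genes entered the test. Serpina6 went from 2357 ± 142 to 158 ± 115 and Otc from 3356 ± 204 to 360 ± 70.5. The log2 fold changes of Serpina6, Sucnr1, Otc, Rgs16, Cyp2b13, Hpd and Hamp2 were -4.00, -3.55, -3.18, -3.12, -3.01, -2.98 and -2.78. The largest rises were in Gstm3, a glutathione transferase, from 155 ± 85.2 to 1059 ± 239 (log2 fold change 2.74, SE 0.26, adjusted p = 2.31e-05, limma), Mmd2 (2.12), Ncmap (1.93), Wfdc2 (1.88), Asns, the asparagine synthetase (1.79), Gpc1 (1.69), the imprinted noncoding RNA Meg3 (1.65), the E-cadherin gene Cdh1 (1.64), Fkbp11 (1.55) and the steroidogenic Cyp17a1 (1.52). Wild-type Ncmap and Asns lay below the filter signal of 24.0 too, so their exact folds and ranks are uncertain. Probe sets of the glutathione transferase and Cyp2 families can take signal from related members, so values for Gstm3, Gsta4 and the Cyp2 genes are uncertain in that respect.

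Of 7989 genes tested in liver, 807 passed the threshold in limma, 388 higher and 419 lower in knockout, and 142 of them changed at least 2-fold, 37 higher and 105 lower. In the simulation of the liver fit 17 of 173 calls were false, more than the threshold states, so the 807 genes may hold more false calls than that as well. The groups did not overlap for 1270 genes (15.9%, where chance gives 2.86%). With all 16 arrays in 1 fit, 328 genes passed, 110 higher and 218 lower.

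Genes of amino acid breakdown fell in knockout liver. Of 37 tested members of the amino acid catabolism list, 19 were lower, 4 were higher and 14 did not pass (7 higher and 23 lower when adjusted over the list alone). The list was lower than other genes (median log2 fold change -0.32, adjusted p = 5.41e-10, limma camera), with an adjusted p = 0.149 with an estimated correlation. Prodh, which begins proline breakdown, went from 840 ± 35.7 to 149 ± 16.3, Sardh, the sarcosine dehydrogenase, from 1748 ± 170 to 331 ± 64.4, and Aadat from 915 ± 77.6 to 153 ± 41.1. Along tyrosine breakdown, Tat (-0.67), Hpd (-2.98), Gstz1 (-1.32) and Fah (-1.20) fell, while Hgd rose by 0.33 (12 of 20 other settings). Tdo2, which opens tryptophan breakdown, had a log2 fold change of -1.52, Abat one of -2.07 and the alanine transaminase Gpt one of -0.76. Ftcd (0.89), Got1 (0.64) and Kmo (0.42) rose.

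Branched-chain amino acid catabolism fell as a group. Of 19 tested members in liver, 12 were lower, 0 higher and 7 did not pass (14 lower when adjusted over the list alone). The median log2 fold change was -0.59 (adjusted p = 1.64e-13, limma camera), with an adjusted p = 0.149 with an estimated correlation. Ivd, of leucine breakdown, went from 541 ± 74.8 to 99.5 ± 9.30 (log2 fold change -2.27, SE 0.12). Dbt (-1.28), Bckdhb (-1.25) and Bckdha (-0.43), subunits of the branched-chain ketoacid dehydrogenase, fell, as did Aldh6a1 (-1.27) and Mmut (-1.10), which act further down these pathways.

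The urea cycle list did not move one way. Of 7 tested members, Otc and Nags (-0.60) fell, Asl (0.73), Slc25a13 (0.41) and Slc25a15 (0.38) rose, and 2 did not pass (5 higher and 2 lower when adjusted over the list alone; adjusted p = 0.367, limma camera). The median of the list was 0.23 and its mean -0.27. Of 14 tested members of the gluconeogenesis list, Mdh2 (0.84), Pgam1 (0.58) and Tpi1 (0.41) rose and 0 fell (3 higher when adjusted over the list alone), and the list did not pass (adjusted p = 0.125, limma camera). Pck1, G6pc and Fbp1, which encode the committed enzymes of glucose output and were chosen after their values were seen, had log2 fold changes of -0.06 (SE 0.09), -0.20 (SE 0.29) and -0.01 (SE 0.05), none past the threshold.

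Cholesterol synthesis genes were lower in knockout liver, with 7 of 18 tested members lower, 0 higher and 11 not passing (10 lower when adjusted over the list alone). The list median was -0.47 (adjusted p = 1.27e-06, limma camera; adjusted p = 0.149 with an estimated correlation). Msmo1 (-1.48), Hmgcs1 (-1.14), Idi1 (-0.86) and Cyp51 (-0.72) were among them. Of 18 tested fatty acid and triglyceride synthesis genes, 5 were lower, including Fasn (-1.22), Srebf1 (-1.07) and Me1 (-0.96), and 2 higher, including Acacb (0.83), and the list did not pass (adjusted p = 0.267, limma camera; 4 higher and 5 lower when adjusted over the list alone). In bile acid synthesis and transport, 5 of 17 members were lower and 1 higher (6 lower and 1 higher when adjusted over the list alone), with Cyp7b1 at -1.73 and Cyp27a1 at -0.46 (adjusted p = 0.0115, limma camera; adjusted p = 0.332 with an estimated correlation).

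Of 20 tested glucocorticoid-responsive genes, 8 were lower and 1, Cdkn1a (1.05), was higher (10 lower and 1 higher when adjusted over the list alone). Cdkn1a passed in 10 of 20 other settings. Per1 (-1.17), Cebpb (-0.95), Dusp1 (-0.84) and Tsc22d3, from 1167 ± 200 to 596 ± 203, were among the lower (list adjusted p = 9.88e-05, limma camera; adjusted p = 0.235 with an estimated correlation). Of 33 xenobiotic metabolism genes, 14 were lower, among them Gsta4 (-2.32), Cyp2c37 (-1.21) and the nuclear receptor gene Nr1i3 (-1.20), and 5 higher, among them Gstm3 and Cyp2d9 (1.51), with 17 lower and 6 higher when adjusted over the list alone (list adjusted p = 0.000142, limma camera; adjusted p = 0.305 with an estimated correlation). In the Kruppel-like factor family, 5 of 10 tested members were lower both over all genes and when adjusted over the list alone: Klf15, Klf10 (-1.50), Klf4 (-0.87), Klf1 (-0.85) and Klf2 (-0.64) (adjusted p = 2.35e-05, limma camera; adjusted p = 0.149 with an estimated correlation). Klf2 passed in 11 of 20 other settings. Without Klf15 itself the list median was -0.25, against -0.44 with it, and the mean was -0.47. The list without Klf15 had an adjusted p = 0.000976 (limma camera), and an adjusted p = 0.208 with an estimated correlation.

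The lists that rose in liver were oxidative phosphorylation and TCA cycle and the integrated stress response. Of 38 members of the former, 7 were higher, among them Mdh2, Sdhd (0.58) and Fh1 (0.53), and 2 lower, Idh2 (-0.85) and Sdhb (-0.71) (9 higher and 4 lower when adjusted over the list alone; adjusted p = 0.0102, limma camera; adjusted p = 0.653 with an estimated correlation). Of 23 stress response genes, Asns, Sdf2l1 (0.86), Shmt2 (0.37) and Xbp1 (0.33) rose and 0 fell (5 higher when adjusted over the list alone; adjusted p = 0.0258, limma camera; adjusted p = 0.449 with an estimated correlation). Asns passed in all 19 other settings in which it was tested, Shmt2 in 11 of 20, Xbp1 in 7 of 20 and Sdf2l1 in 5 of 20, and the list passed in 15 of 22. The proteolysis and interferon lists were lower, each with 1 member past the threshold, Ctsl (-0.66) and Gbp3 (-0.67) (adjusted p = 0.0161 and 0.0118, limma camera; adjusted p = 0.449 and 0.591 with an estimated correlation). Gbp3 passed in 12 of 20 other settings, as did Marco below. In all, 11 of 21 lists passed with the preset correlation, 0 with an estimated one and 7 with fry. Of the cell type marker lists, 0 of 7 tested in liver passed with camera at either correlation or with fry, and the macrophage list had the smallest p (p = 0.0279 unadjusted, adjusted p = 0.195, limma camera), with Marco, chosen after its value was seen, at 1.58. Marco was the only 1 of 12 macrophage markers past the threshold, 11 did not pass, and the list median was 0.19.

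**Figure D2:**
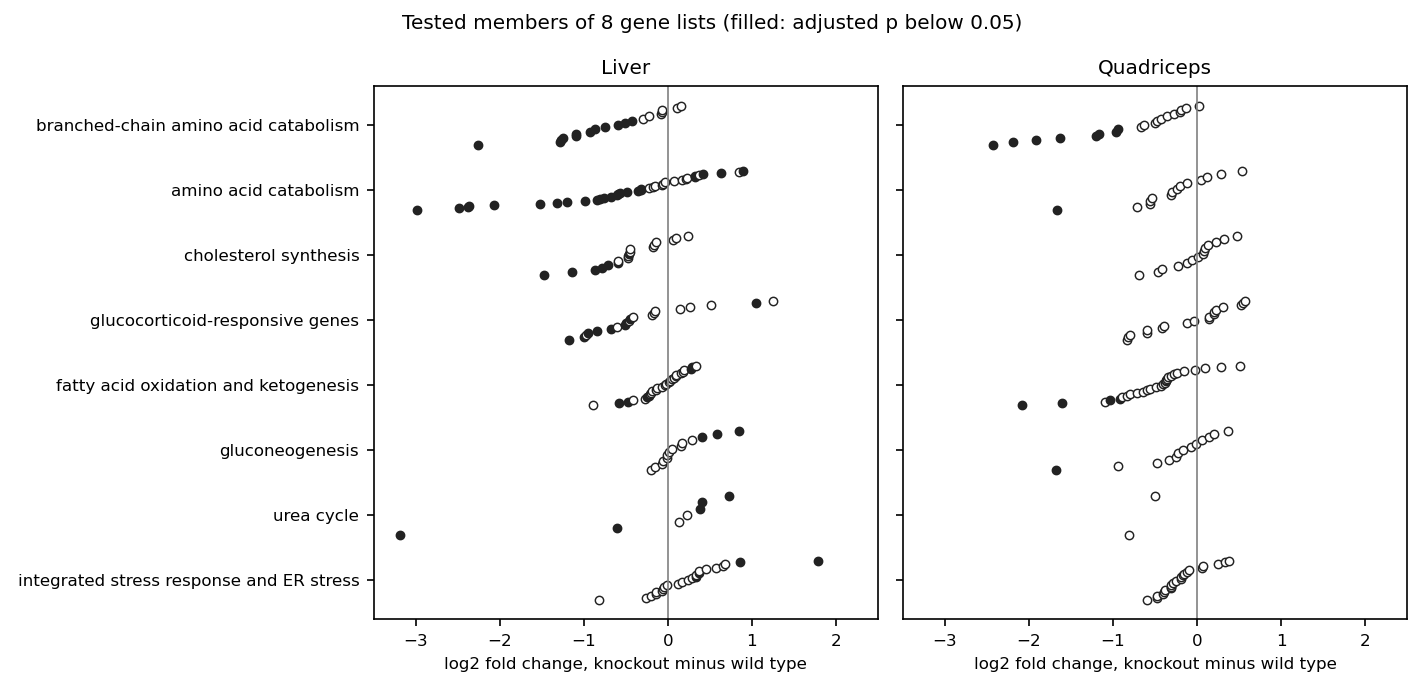
Log2 fold change, knockout minus wild type, of each tested member of 8 gene lists in liver and quadriceps, sorted within a list, with filled points for adjusted p below 0.05. In liver 12 of 19 branched-chain amino acid genes and 19 of 37 other amino acid catabolism genes were lower, in quadriceps 8 of 19 and 1 of 14; the urea cycle list had too few members in quadriceps for a list test.

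In knockout quadriceps, the largest falls beside Klf15 were in Adhfe1, from 462 ± 109 to 4.56 ± 2.44 (log2 fold change -4.52, SE 0.19, adjusted p = 1.49e-10, limma), Fgfbp1, which binds fibroblast growth factors (-2.48), Aldh6a1 (-2.43), Bckdhb (-2.19), Selenbp1 (-2.10), Gstm2 (-2.09), the acyl-CoA thioesterase Acot1 (-2.08), the aldehyde dehydrogenase Aldh2 (-2.05) and Gstk1 (-2.04). For Aldh2, 2 other probe sets above the filter differed in sign from the one used. Aldh6a1 went from 943 ± 124 to 168 ± 59.6 and Bckdhb from 479 ± 39.9 to 93.3 ± 21.0. The rises were Jph1, of the junction between the surface membrane and the calcium store (1.29), the innate immune sensor Sting1 (1.18), Usp13 (1.17) and Ap2b1 (0.98). Jph1, Usp13 and Ap2b1 passed in 11 of 24 other settings and Sting1 in 11 of 23. The knockout signals of Adhfe1, Fgfbp1, Acot1 and Prodh lay below the filter signal of 22.6, so their exact folds and ranks are uncertain.

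Of 7991 genes tested in quadriceps, 78 passed the threshold in limma, 4 higher and 74 lower, and 53 of them changed at least 2-fold. The groups did not overlap for 657 genes (8.22%, where chance gives 2.86%). The median log2 fold change of all tested genes was -0.18 with median scaling, -0.06 with quantile normalization and -0.48 without scaling. Without knockout quadriceps 8, 1774 genes passed, 116 higher and 1658 lower, the 78 among them, and with quantile normalization and without that array 657 passed, 242 higher and 415 lower, including 75 of the 78. With all arrays, quantile normalization kept 45 of the 78 and trimmed-mean scaling 50. Leaving out wild-type quadriceps 1, 2, 3 or 4 gave 43, 33, 32 and 51 genes and the scan day as a block gave 1771. Only knockout quadriceps 8 was scanned on the later day, so that block amounts to leaving it out.

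Branched-chain amino acid catabolism fell in quadriceps as well. Of 19 tested members, 8 were lower, 0 higher and 11 did not pass (12 lower when adjusted over the list alone). The list median was -0.63, and -0.44 relative to the median of all tested genes (adjusted p = 6.57e-12, limma camera; adjusted p = 0.244 with an estimated correlation). Beside Aldh6a1 and Bckdhb these were Dbt (-1.91), the transaminase Bcat2 (-1.63), Mmut (-1.20), Ivd (-1.17), Bckdha (-0.97) and Acadsb (-0.94), the last passing in 14 of 24 other settings. With quantile normalization the list median was -0.41 (adjusted p = 2.42e-11, limma camera). Of the other amino acid catabolism genes, 1 of 14 passed, Prodh (-1.66; 2 lower when adjusted over the list alone), and that list did not pass (adjusted p = 0.368, limma camera).

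Of 28 tested fatty acid oxidation genes in quadriceps, 24 did not pass and 4 were lower, Acot1, Ehhadh (-1.61), the lipid-sensing receptor Ppara (-1.03) and Echs1 (-0.91), and 7 lower when adjusted over the list alone. Acot1 and Ehhadh passed in all 23 other settings in which they were tested, Echs1 in 12 of 24 and Ppara in 11 of 24. The list median was -0.42, and -0.23 relative to all tested genes (adjusted p = 0.000636, limma camera; adjusted p = 0.735 with an estimated correlation; 0.163 with fry). Fbp2, the muscle fructose bisphosphatase, was the 1 gluconeogenesis gene of 13 past the threshold (-1.68), and Klf10 (-1.95) and Klf4 (-1.07) fell beside Klf15 among 12 tested Kruppel-like factors (Klf4 in 14 of 24 other settings), while those lists did not pass (adjusted p = 0.965 and 0.305, limma camera; 0.953 for the latter without Klf15).

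The proteolysis and autophagy, fast fibre and oxidative phosphorylation lists passed as higher and the cell cycle list as lower in quadriceps with 0 members past the threshold in limma (1, 0, 1 and 4 at an unadjusted p under 0.05; adjusted p = 0.00694, 0.000312, 0.0202 and 0.0202, limma camera; adjusted p = 0.735, 0.735, 0.913 and 0.735 with an estimated correlation). The medians were 0.13, 0.32, -0.03 and -0.47, the oxidative phosphorylation median and test thus differing in sign. The myofibre (median 0.32, adjusted p = 0.00896, limma camera) and macrophage marker lists (0.08, adjusted p = 0.0170) passed as higher, with an adjusted p = 0.705 with an estimated correlation and 0.594 with fry for both. Of 9 and 10 members, 0 passed in limma, nor did any at an unadjusted p under 0.05, and Myh4 and Atp2a1 are in both the myofibre and the fast fibre list. Without knockout quadriceps 8 the fast fibre median was -0.03 (adjusted p = 0.115, limma camera), the proteolysis median -0.10 (adjusted p = 0.0516) and the cell cycle median -0.50 (adjusted p = 0.115). With quantile normalization the fast fibre median was 0.02 (adjusted p = 0.277), and without scaling the proteolysis median was -0.22 (adjusted p = 0.148). Adipoq, made by adipocytes and named outside the rule, was 745 ± 215 in wild type and 387 ± 293 in knockout (log2 fold change -1.12, adjusted p = 0.155, limma), and the adipocyte list did not pass (adjusted p = 0.0781, limma camera). In all, 6 of 21 lists passed, 0 with an estimated correlation and 1, the branched-chain list, with fry.

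The interaction asked whether the knockout effect differed between the tissues. The largest terms on the side of liver being higher were Gstm3 (3.14), Mmd2 (2.44), Fgfbp1 (2.33), Slc25a25, a mitochondrial carrier (2.13), and Tubb2a (2.05), and on the other side Serpinb1a (-4.98), Serpina6 (-4.15), Sucnr1 (-3.39), Cyp2b13 (-3.31) and Hpd (-3.22). For Mmd2 and the 5 negative terms, the mean quadriceps signals were below the filter in both genotypes, and for Fgfbp1 those in liver were. Slc25a25 was tested in both, with a log2 fold change of 0.67 in liver (adjusted p = 0.290, limma) and -1.46 in quadriceps (adjusted p = 0.0282). Its quadriceps call passed in 15 of 24 other settings. Of 8966 genes, 172 passed in limma, 103 positive and 69 negative. Median centring of the log2 values gave 1023, 884 positive and 139 negative, no scaling gave 287, 247 positive and 40 negative, and leaving out knockout quadriceps 8 gave 1659, 1446 positive and 213 negative. In a list test chosen after seeing the data, the knockout effect on cholesterol synthesis was lower in liver than in quadriceps (adjusted p = 4.31e-06, limma camera, 0.0406 with an estimated correlation and 0.0591 with fry). It was so over the 14 members tested in both tissues (adjusted p = 8.55e-09, limma camera, 0.0127 with an estimated correlation and 0.0439 with fry). In quadriceps alone 0 of the 14 tested members passed, and the list median was 0.04 (adjusted p = 0.280, limma camera). For the interaction, 1 of the 18 cholesterol synthesis members passed in limma, and 2 had an unadjusted p under 0.05. The list tests of the interaction were not repeated under other scalings or without knockout quadriceps 8. Amino acid catabolism passed as well (adjusted p = 3.42e-09, limma camera; adjusted p = 0.0226 with an estimated correlation), but 23 of its 37 members were not tested in quadriceps. Over the 14 others its adjusted p = 0.000487 (limma camera), and its adjusted p = 0.441 with an estimated correlation. The branched-chain list passed in neither test (adjusted p = 0.9997 and 0.847, limma camera).

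The overlap of the tissues was tested over the 7014 genes tested in both. Lower in both were 38 genes, where 2.96 were expected for independent lists (Fisher's exact test, one-sided, p = 8.91e-35), and 0 were higher in both, where 0.0893 were expected. That test takes genes as independent units, so its p does not measure the spread between samples. Klf15 itself is among the 38. Station followed genotype alike in both tissues, so a shared station effect cannot be told apart from the knockout in this overlap. Parp2, named outside the rule, was higher in liver (0.54) and lower in quadriceps (-0.99), with an interaction term of 1.53 (adjusted p = 0.00129, limma). Its call passed in 11 of 20 other settings in liver and 17 of 24 in quadriceps. Ranked by the smaller change, the shared falls were led by Adhfe1, Klf15, Gstk1 (-2.50 in liver and -2.04 in quadriceps), Prodh (-2.38 and -1.66), Klf10 (-1.50 and -1.95), Selenbp1 (-1.49 and -2.10), Zfp275 (-1.53 and -1.39), the kynurenine aminotransferase Kyat3 (-1.50 and -1.31), the clock regulator Bhlhe40 (-1.28 and -1.33) and Dbt (-1.28 and -1.91). The interaction did not pass for any of these 10 genes, and among the other shared falls it passed for Aldh2 (adjusted p = 0.000741, limma), Bckdhb (0.0179) and Aldh6a1 (0.0296), which fell further in quadriceps, and for Gsta4 (0.0108) and Ivd (0.0140), which fell further in liver. For Aldh2 this rests on the probe set used, from which others differed in sign in quadriceps, as stated above. The quadriceps call of Gsta4 passed in 13 of 24 other settings. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.199 and a Spearman rho of 0.0887. Without knockout quadriceps 8, 139 genes were lower and 6 higher in both.

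**Figure D3:**
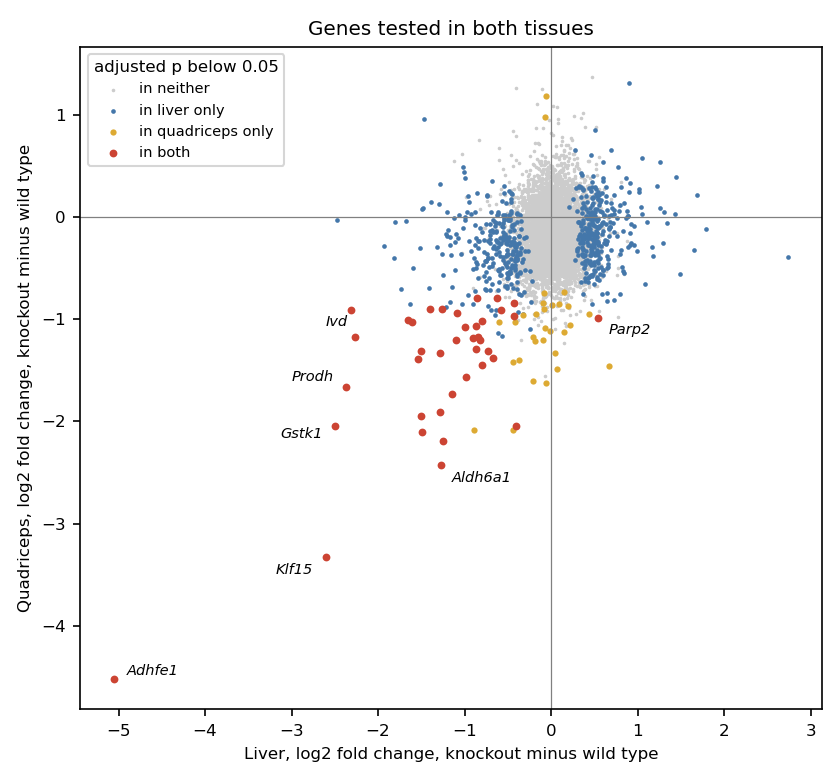
Log2 fold change, knockout minus wild type, in quadriceps (vertical) against liver (horizontal) for the 7014 genes tested in both, coloured by where adjusted p was below 0.05. The 38 genes lower in both lie at lower left, with Adhfe1 at -5.05 and -4.52, and Parp2 is the 1 gene with opposite calls.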

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

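The tests of the scaling, of the noise of 1 array and of the splits that leave out an array or use quantile normalization were chosen only after the results were seen. The test of the wider sex-biased shift was written after Cyp2b13, Hamp2 and Slc22a26 had been seen, and its demand that a bound be passed by more than the spread of the members was added after its result was seen.

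The real grouping of the 8 liver arrays gave 807 genes, and the highest of the other splits into 4 and 4 gave 4. Thus 1 of the 35 splits, the real grouping itself, reached the real count. That is the smallest share the test can give, so it argues against chance but cannot exclude it. The other splits also hold the genotype effect within their groups, which widens their spread. For the interaction, split alike in both tissues, 1 of 35 splits reached the 172 genes, with 5 as the highest other. Those splits break up the genotype effect of each tissue too, so they cannot single out a difference between the tissues. For quadriceps 2 of 35 splits reached the 78 genes, so chance cannot be excluded for that count. The other split, of wild type 1, 2, 3 and knockout 8 against the rest, gave 287 genes with median scaling and 0 with quantile normalization, under which 1 of 35 splits reached the real 63 genes, with 3 as the highest other. The verdict for quadriceps thus depends on the scaling. Knockout 8 was left out after its effect on the count was seen, so each split was also allowed to leave out any 1 array and to use median scaling or quantile normalization. The highest count of the real grouping was then 1774, and 2 of 35 splits reached it, the other with 1835 genes, so chance cannot be excluded for the 1774 either. With quantile normalization alone and the same freedom, 1 of 35 splits reached the real 657, with 475 as the highest other. The 4 other splits with the highest counts, 1055 to 1835 genes, all set knockout 5, 6 and 7 against a group of wild-type arrays and knockout 8, so they hold most of the genotype contrast.

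More quadriceps genes passed without knockout 8 than with it, 1774 against 78. Median scaling as the reason for the larger count is argued against, since with quantile normalization the count without this array was still 10.4 times the count with it. Median scaling may explain why most of those genes fell, since the share of falling genes was 93.5% with it and 63.2% with quantile normalization. Whether the array is noisier stays open: its median deviation from the other knockout arrays was 1.35 times theirs, between the bounds of 1.5 and 1.1 set for the test. Their deviations were taken from means that include knockout 8, which can lower this ratio. Every knockout quadriceps array deviated more from its group (0.213 to 0.296 on the log2 scale) than any wild-type array (0.129 to 0.158). The values of knockout 5, 6 and 7 use means that include knockout 8. They thus cannot tell whether the spread differed between the genotypes beyond that array. The scan of knockout 8 on a later day cannot be told apart from the sample itself, and no biological explanation was tested.

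Genes near Klf15 were set apart, because DNA of the donor strain carried along with a targeted allele could change neighbours. Among the 200 tested genes nearest Klf15 in liver, 28 had changed (14%, against 10% elsewhere, a ratio of 1.40, Fisher's exact p = 0.0736, two-sided). In quadriceps 3 of 200 had, a ratio of 1.58, past the bound of 1.5 set beforehand, but the Fisher's exact p = 0.444 did not pass. The liver ratio lay between the bounds of 1.5 and 1.2, so this explanation stays open in both tissues, and the strain background is not given in the sources used here.

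Cyp2b13, Hamp2 and Slc22a26, known as female-biased in mouse liver, fell in knockout liver. Slc22a26, Acot3 and Elovl3 were named outside the rule. Male animals under female labels are argued against, since the lowest Xist signal in knockout liver was 94.6% of the wild-type mean and 0 Y-linked genes were at least 5 times higher. A wider shift towards the male pattern could not be decided: the other 8 female-biased genes had a median log2 fold change of -0.0477 (SD 0.865) and 10 male-biased genes one of -0.205 (SD 1.001). Those medians met the bound set beforehand against such a shift, but by less than the spread of the members. Of 6 further members past the threshold, 3 (Acot3, Cyp2d9 and Gstp1) moved towards the male pattern and 3 (Cyp17a1, Elovl3 and Cyp7b1) away from it. Acot3 passed in 12 of 20 other settings.

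The knockout effect differed between the tissues by the interaction for Gstm3 (3.14 on the log2 scale), Mmd2 (2.44), Fgfbp1 (2.33), Slc25a25 (2.13), Tubb2a (2.05), Serpinb1a (-4.98), Serpina6 (-4.15), Sucnr1 (-3.39), Cyp2b13 (-3.31) and Hpd (-3.22). Mmd2 and the 5 negative terms had quadriceps signals below the filter in both genotypes, and Fgfbp1 had liver signals below it, so a fall could hardly be seen there and the exact terms are uncertain. A large rise could have been seen, and Mmd2 had none in quadriceps (10.4 in wild type and 4.41 in knockout). By the list test it differed for amino acid catabolism (adjusted p = 3.42e-09, limma camera), cholesterol synthesis (4.31e-06), xenobiotic metabolism (1.06e-05), glucocorticoid-responsive genes (0.000912), interferon response (0.00225), fast fibre genes (0.00354), proteolysis and autophagy (0.00415), bile acid synthesis and transport (0.00415) and fatty acid oxidation (0.0276), and of these the first pair passed with an estimated correlation. The glucocorticoid, interferon, fast fibre and proteolysis lists had 0 members past the threshold in limma. Their medians were -0.04, -0.12, -0.29 and -0.15, against 0.18 for all tested genes (0.07 with quantile normalization). The fast fibre list had too few members tested in liver for a list test, so its difference rests mainly on quadriceps. Its quadriceps call was lost with quantile normalization (median 0.02, adjusted p = 0.277, limma camera). Many members of other lists were not tested in quadriceps. These were 23 of 37 for amino acid catabolism, 20 of 33 for xenobiotic metabolism and 13 of 17 for bile acids. Members with so little signal there could hardly fall. Over the genes tested in both tissues, cholesterol synthesis passed with an estimated correlation (adjusted p = 0.0127), amino acid catabolism with the preset one alone (adjusted p = 0.000487, and 0.441 with an estimated correlation), and xenobiotic metabolism (adjusted p = 0.650) and bile acids (0.2496) with neither.

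Of 282 groups of 4 arrays for genes named here, 22 had 1 array far from the others, where chance flags about 1 in 20 groups. In liver wild type, number 4 was lowest for Tat (its gap was 0.885 of the group's range), Per1 (0.957) and Klf4 (0.847), number 1 was highest for Cdkn1a (0.838), number 2 for Selenbp1 (0.893) and number 3 for Parp2 (0.885). In liver knockout, number 5 was highest for Aadat (0.880) and lowest for Fh1 (0.833) and Gstk1 (0.931), number 6 was lowest for Me1 (0.871) and highest for Selenbp1 (0.895), number 7 was lowest for Mmd2 (0.934, a signal of 318 against 521 to 539), and number 8 was highest for Bckdhb (0.854) and lowest for Bckdha (0.840) and Gys2 (0.926). In quadriceps wild type, number 2 was lowest for Klf15 (0.904) and highest for Bckdhb (0.837), and number 3 was highest for Kyat3 (0.859). In quadriceps knockout, number 8 was lowest for Jph1 (0.840, a signal of 125 against 371 to 454), number 7 highest for Selenbp1 (0.883), number 5 for Prodh (0.859) and number 6 for Kyat3 (0.834).

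Of the probe sets with several gene symbols or none, which entered no gene test, 97 of 1092 tested in liver passed the threshold with every probe set as its own feature (39 higher and 58 lower), and 4 of 1053 in quadriceps (0 higher and 4 lower).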

How the results depend on the processing

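The liver result held best. Its count of 807 genes stayed within 1.5 times under the pseudocounts, filters, normalizations, probe set rules and module block tried. The genes themselves were not always the same. Of the 807, 802 passed in the same direction with pseudocount 64, 780 with quantile normalization, 691 with the module block and 606 without a filter. With the mean of all probe sets, 645 of the 792 still tested did. With all 16 arrays in 1 fit, 328 passed. There the liver fold changes were unchanged, and the spread was estimated over both tissues. In the separate fits the median SE was 0.133 in liver and 0.216 in quadriceps. Leaving out 1 array gave 572 to 751 genes in liver, 32 to 1774 in quadriceps, 117 to 1659 for the interaction, 22 to 145 for genes changed in both tissues, 9 to 12 lists in liver and 2 to 7 in quadriceps. Leaving out knockout quadriceps 8 gave the 1774, 1659 and 145 genes and the 2 lists. In quadriceps 46 genes passed without a filter, 42 without the variance trend, 940 with median centring, 323 with all 16 arrays in 1 fit and 1771 with the scan day as a block. For the interaction 92 and 290 passed with pseudocounts 1 and 64, 360 with quantile normalization, 1023 with median centring, 262 with the mean of all probe sets and 1662 with the scan day as a block. In both tissues 125 genes changed with median centring and 144 with the scan day as a block, which left 2 lists in quadriceps. The scan day block sets knockout quadriceps 8 alone apart, so it is not a separate check from leaving out that array. Both settings count in the tallies of other settings for quadriceps genes. So do quantile normalization and trimmed-mean scaling without knockout 8, which leave out the same array.

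Among the settings chosen after seeing the data, quadriceps gave 132 genes without scaling, 153 with the module as a block, and 657 and 646 without knockout 8 under quantile normalization and trimmed-mean scaling. The interaction gave 287 without scaling, 319 with trimmed-mean scaling, and 922 and 876 under the same pair of settings without knockout 8, where 98 and 101 genes changed in both tissues. The cause of these differences was not tested beyond the weighing of knockout 8.

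Correlations of same-numbered arrays between the tissues ran from -0.0980 to 0.0507, which gave no sign of pairing. Liver and quadriceps of the same animal need not correlate, so this cannot tell whether equal numbers are the same animal. With the replicate number as a block, 136 genes passed for the interaction, 333 in liver and 326 in quadriceps, the last pair in the fit of all 16 arrays. Only numbers 1 and 4 correlated better with their own number than with the others of their genotype. The station as a block could not be fitted because it follows genotype, chip lots each held 1 array, and all liver arrays shared 1 scan day, so those blocks were not run.

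With an estimated correlation 0 lists passed in either tissue, and with fry 7 in liver and 1 in quadriceps. In quadriceps, oxidative phosphorylation passed as lower without scaling (median -0.383, adjusted p = 0.0162). It lost its call with quantile normalization (-0.0649), with the scan day block (-0.349), without knockout 8 (-0.349, and -0.0775 and -0.0638 with quantile normalization and trimmed-mean scaling) and with fry, where its median is the same -0.0288 as before. Without knockout 5 its median was 0.184. Slow fibre genes passed as lower without scaling (-0.79), and the cell cycle list lost its call without a filter (-0.25, adjusted p = 0.939). Of the genes named and past the threshold, 65 of 99 in liver and 16 of 33 in quadriceps passed under every setting in which they were tested, and 0 changed sign past the threshold. Signals near the background limit folds for Adhfe1, Serpinb1a and Sucnr1 in knockout liver.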

Other observations

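Some groups were not described above. In liver, of 22 acute phase and inflammation genes, 0 passed in limma (4 at an unadjusted p under 0.05), and of 21 extracellular matrix genes 1 did, a fall in Ccn2 (-0.64), with list tests at an adjusted p = 0.843 for both (limma camera). Of 16 circadian clock genes, Bhlhe40, Per1 and Tef (-0.63) fell and 0 rose (Tef passed in 11 of 20 other settings), and the list did not pass (adjusted p = 0.0611, limma camera). Of 21 glycolysis genes, 3 fell, Pdk1 (-1.51), a kinase that restrains pyruvate dehydrogenase, Pklr (-0.74) and Pygl (-0.43), and 2 rose, Ldha (0.26) and Gys2 (0.55), with 4 lower and 3 higher when adjusted over the list alone. Pygl passed in 13 and Gys2 in 8 of 20 other settings, and knockout 8 lay at 736 against 1203 to 1251 on the other knockout arrays. Of 27 fatty acid oxidation genes in liver, 4 fell and 2 rose, with Echs1 at -0.58, and that list did not pass (adjusted p = 0.125, limma camera).

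In quadriceps, slow fibre genes varied widely between knockout arrays. Myh7 was 1947 ± 562 in wild type and 1398 ± 1178 in knockout, a log2 fold change of -1.28 (SE 0.74, adjusted p = 0.380, limma), and 0 of 14 slow fibre genes passed in limma, nor did any at an unadjusted p under 0.05. Of 17 fatty acid and triglyceride synthesis genes 0 passed over all genes in limma (5 at an unadjusted p under 0.05) and 4 were lower when adjusted over the list alone (list adjusted p = 0.0618, limma camera). Adipocyte markers lay lower beside them. Of 6 tested, 0 passed in limma and 3, Adipoq among them, were lower at an unadjusted p under 0.05. Whether these synthesis genes follow the share of fat cells in the samples was not tested.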
